A study of Mus musculus with 21 samples.

How the data were processed

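The data were DNase-seq peak lists from livers of individual, untreated male CD-1 mice aged 8 to 10 weeks. DNase-seq cuts nuclei lightly with DNase I and sequences the released short fragments, so that stretches of open chromatin (DNase hypersensitive sites) appear as peaks of reads. Per the labels, part of each liver went to an electrophoretic mobility shift assay, in which a protein extract is tested for binding to a DNA probe, and the liver was classed by its STAT5 DNA-binding activity when the mouse was killed. STAT5 is the transcription factor that the growth hormone receptor activates, and growth hormone reaches the male mouse liver in pulses. The class STAT5_High held 8 livers and the class STAT5_Low held 10. A further 3 livers of the 21 in the series, 2 classed high and 1 classed low by the binding assay, were titled outlier by the submitters because their DNase-seq profile resembled the other class; they were not analysed here. For 2 of the 3, the treatment label names the other class than the title. The groups compared were therefore selected in part on the measurement that is compared, which favours a difference between them.

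Per the file headers, each liver's peaks were called on its own reads with MACS2 version 2.1.0.20150731, without a control library, keeping duplicate reads, with a shift of -100 and an extension of 200 bases, a tag size of 40 and a q cutoff of 0.05. Bowtie2, MACS2 and the mouse build mm9 are named in the submitters' processing notes. The authors' -log10 q of each peak, as deposited, is MACS2's significance of that peak within its library. The deposited fold enrichment is MACS2's ratio of the reads at the summit to the local background of the same library. The authors' pileup is the signal at the summit, the number of extended reads that overlap there, and it was not scaled between libraries. These values are the authors' and belong to each peak. They were used to describe, rank or filter peaks within a list, and the median fold enrichment of a list was compared between the classes. The 2 combined lists were called, per the file headers, on pooled reads of a class: their 128701824 and 184748725 tags equal the sums over the livers of STAT5_High and STAT5_Low.

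The number of tags per library, taken from the headers, set the depth. It ran from 12890880 to 23395665 tags and was lower in STAT5_High than in STAT5_Low livers. A weak site can be open in a liver and still lack a peak at this depth, so absence of a peak means that none was called. Peak coordinates in the lists are 1-based. Every peak lay within the chromosomes of the NCBIM37 reference (mm9), in which chromosome 1 has 197195432 bases and the highest peak end was 197111769. Genes were taken from the GENCODE annotation of the same build. Sequences are those of the reference, and variants of the outbred CD-1 stock were not considered. Any pair of lists shared at most 0.0688% of peaks with identical start and end, so no library appeared to be deposited more than once.

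Peaks of the 18 lists that shared 1 bp or more were merged into a union of 68362 regions, and a liver occupied a region when its list held a peak there. At the regions, only presence was compared between livers, since no value in the lists is scaled between libraries. The main test was a two-sided Fisher's exact test per region on the numbers of occupied livers of the 8 and 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on the 15631 regions occupied in 5 to 13 of the 18 livers, those in which the smallest possible p is at most 0.01, a filter that does not use the classes. The number of peaks, the bases covered and the similarity of lists (the Jaccard index, shared bases over the bases in either list) were compared with two-sided exact permutation tests over all 43758 assignments of 8 of 18 livers. Label prefixes put the livers in 3 collections, G74A (2 STAT5_High and 5 STAT5_Low), G92 (3 and 2) and G99 (3 and 3); the labels do not say what a collection is, and values within each are given.

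Regions were assigned to a gene when they overlapped it or lay within 10 kb, and otherwise named by the nearest protein-coding gene. Of 286 gene names in 16 lists fixed beforehand (STAT5 targets, male-biased and female-biased liver genes, hepatocyte genes, the growth hormone and IGF axis, bile acid and sterol, lipid, glucose and amino acid, circadian clock, immediate early and stress, acute phase, and markers of macrophages, endothelium, stellate cells, cholangiocytes and lymphocytes), 284 matched the annotation. Each list was tested in each direction (32 tests) with a two-sided Fisher's exact test against the other tested regions, and a second adjustment was made over a list alone. A promoter was the stretch within 1 kb of a transcription start, and the STAT5 motif was TTCNNNGAA. The regions named are, per direction, the 12 past the threshold with the largest difference in the share of livers, ties ordered by p and then by the mean rank of the authors' score within the lists; to these were added list genes with a called region within 10 kb, and genes with a tested region of the STAT5 target and hepatocyte lists. Of these, 1 hepatocyte gene and 1 region of the 12 towards STAT5_Low are not reported here. The gene lists, the main tests, this rule and the alternatives below were fixed before the data were examined, and further tests were chosen later. The alternative settings were a stricter score (-log10 q of at least 12.5), the 18673 top peaks of every list, other filters and overlaps, tests stratified by collection or by replicate number, a logistic model with the number of peaks, and leaving out each liver or collection.

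The occupancy test was tested on simulated data of 15631 regions: of 50 regions simulated at 95% of STAT5_High and 2% of STAT5_Low livers 70.0% were called, of 50 at 85% and 15% 8.00% were called, of 50 at 2% and 95% 46.0%, of 50 at 15% and 85% 18.0%, and 0 of 15431 unchanged regions. The test therefore finds mainly regions that are present in nearly all livers of a class and missing in nearly all of the other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.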

Results

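DNase-seq peak lists were available for the livers of 18 male mice, 8 taken when STAT5 DNA-binding activity was high (STAT5_High) and 10 when it was low (STAT5_Low). The series asks how the natural pulses of growth hormone, which activate STAT5 in male liver, change chromatin accessibility. Lists held 18673 to 45144 peaks, and libraries 12890880 to 23395665 tags. Merging all lists gave 68362 regions with a median width of 546 bp, of which 11748 (17.2%) had a peak in all 18 livers and 14763 (21.6%) in a single liver.

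Open chromatin near Igf1, the growth hormone-induced hormone gene of liver, and near Bcl6, a transcriptional repressor, differed between the classes. In STAT5_High livers 153 regions had a peak more often, and 21 had a peak more often in STAT5_Low livers, so that 87.9% of the 174 calls were higher in STAT5_High. A set of 47 regions had a peak in 8 of 8 STAT5_High and 0 of 10 STAT5_Low livers, and 1 region, near the solute carrier gene Slc45a3, had the opposite pattern. Regions near Lifr (the leukaemia inhibitory factor receptor), Cyp7b1 (an oxysterol hydroxylase of bile acid synthesis), Myc, Foxa1 and Onecut1 (liver transcription factors) were among those 47. Calls rested on Fisher's exact test (two-sided, Benjamini-Hochberg over 15631 regions), with 1.11% of tested regions called. At an unadjusted p under 0.05, 940 regions leaned towards STAT5_High and 1265 towards STAT5_Low. With equal numbers of top peaks, where only 8178 regions were tested, 969 and 501 did. A logistic model with the number of peaks gave 1478 and 978, by an approximate test in place of the exact one. The change of test and the fitted number of peaks were not told apart. Within each of the 3 collections, all 153 and all 21 regions went the same way, which their near-complete differences over all livers largely fix. The 153 were occupied in a mean of 94.1% of STAT5_High and 0.392% of STAT5_Low livers in G74A, 91.5% and 6.54% in G92, and 97.6% and 3.27% in G99. The 21 were occupied in 9.52% of STAT5_High and 96.2% of STAT5_Low livers in G74A, 0.0% and 88.1% in G92, and 4.76% and 93.7% in G99. An exact test stratified by collection called 0 regions in either direction (827 and 914 at an unadjusted p under 0.05; smallest adjusted p 0.0775, at the smallest p the strata allow, 0.000238). Leaving out any collection also left 0 calls. The count of 153 became 251 without STAT5_High replicate 4. The count of 21 became 43, 33, 35 and 36 without STAT5_High replicates 1, 2, 6 and 8, and 33, 33 and 43 without STAT5_Low replicates 1, 4 and 6. Because the submitters set aside 3 livers whose profile went against their class, the counts describe only the livers kept.

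The 12 regions with the largest difference towards STAT5_High each had a peak in 8 of 8 STAT5_High and 0 of 10 STAT5_Low livers (Fisher's exact p = 2.29e-05, the smallest possible; adjusted p = 0.00744). Intronic regions (mm9) lay in Igf1 (chromosome 10, 87325416 to 87326040), in Lifr (chromosome 15, 7085907 to 7086454), in the zinc-finger repressor gene Zbtb20 (chromosome 16, 43234241 to 43234928), in Gmds, an enzyme of GDP-fucose synthesis (chromosome 13, 32284979 to 32285655), and in the tRNA-modifying enzyme gene Trit1 (chromosome 4, 122704018 to 122704671). Intergenic regions lay 2662 bp from Cyp7b1 (chromosome 3, 18146000 to 18146664), 12227 bp from Nufip1 (chromosome 14, 76549413 to 76550031), 19663 bp from Larp4b (chromosome 13, 9072976 to 9073488), 70184 bp from Onecut1 (chromosome 9, 74639123 to 74639544), 91597 bp from Bcl6 (chromosome 16, 24080535 to 24081097), 173499 bp from Myc (chromosome 15, 61995428 to 61996067) and 497563 bp from Pik3c3 (chromosome 18, 29933977 to 29934838). The nearest gene is a name for a region at such distances, not a measured target. All 12 remained called when any single liver was left out, which their complete differences largely fix. All 12 kept their direction without a call in the test stratified by collection. In the combined STAT5_Low list of pooled reads, the regions at Igf1, Lifr, Cyp7b1, Nufip1, Bcl6, Myc and Pik3c3 did have a peak. Those at Zbtb20, Gmds, Trit1, Larp4b and Onecut1 did not.

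The 12 regions with the largest difference towards STAT5_Low began with the intergenic region 10455 bp from Slc45a3 (chromosome 1, 133889995 to 133890626), found in 0 of 8 STAT5_High and 10 of 10 STAT5_Low livers (Fisher's exact p = 2.29e-05, adjusted p = 0.00744). The other 11 had a peak in 0 of 8 and 9 of 10 livers (Fisher's exact p = 0.000411, adjusted p = 0.0370). Intronic ones lay in Hlf, a transcription factor gene with circadian expression (chromosome 11, 90217996 to 90218534), the tryptophan-degrading Ido2 (chromosome 8, 25676732 to 25677271), the prostaglandin reductase gene Ptgr1 (chromosome 4, 58998006 to 58998507), the DNA topoisomerase gene Top2b (chromosome 14, 17212558 to 17213084), Fam81a (chromosome 9, 69956990 to 69957584) and Grtp1 (chromosome 8, 13190210 to 13190765). A region in the UTR of Zbtb39 (chromosome 10, 127182873 to 127183367) and intergenic ones 305 bp from the mitochondrial carrier gene Slc25a47 (chromosome 12, 110095329 to 110096231), 6370 bp from Rassf8 (chromosome 6, 145688473 to 145688898) and 20735 bp from Hnrpll (chromosome 17, 80407514 to 80408092) were also among them. The mean rank of the authors' score of their peaks within the lists was at the 18 to 43.8 percentile. With the stricter score 0 of the 12 could be tested.

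**Figure D1:**
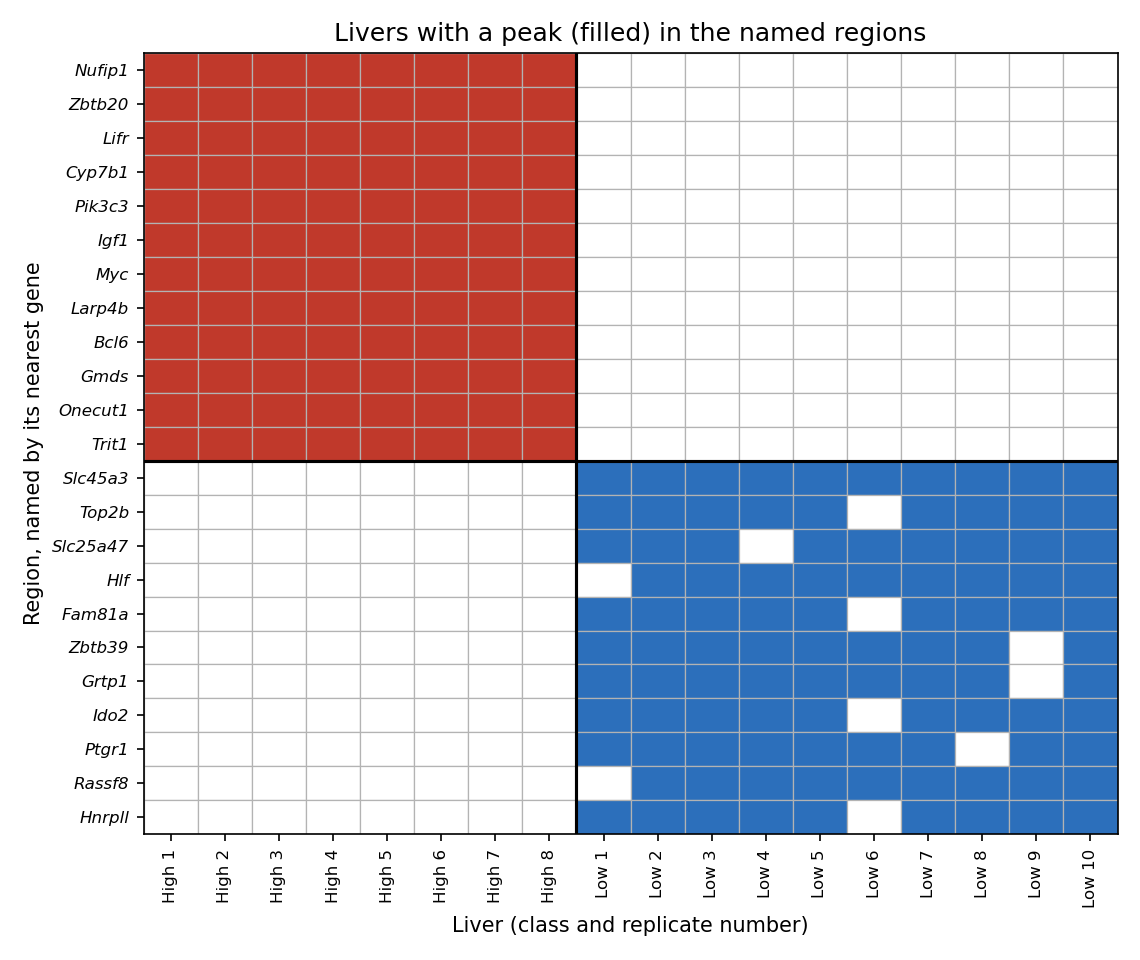
Livers (columns, class and replicate number) with a peak (filled) in 23 of the 24 regions with the largest differences, each named by its nearest gene; the upper 12 were called towards STAT5_High and the lower 11 towards STAT5_Low. The upper 12 are filled in 8 of 8 STAT5_High and 0 of 10 STAT5_Low livers.

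Igf1 was the nearest gene of 3 regions higher in STAT5_High, more than any other gene. A second intronic region (chromosome 10, 87364671 to 87365053) and an intergenic one 62072 bp from the gene (87258328 to 87258938) also had a peak in 8 of 8 STAT5_High and 0 of 10 STAT5_Low livers. The gene spans 87321010 to 87399792, and of the 21 regions of the union that overlap it or lie within 10 kb, 5 were occupied in all 18 livers, so the locus held peaks in both classes. Each of the 3 called regions contained the STAT5 motif: TTCCTGGAA at 87325728 to 87325736, 4.0 bp from the centre of the first intronic region, TTCTCAGAA at 87364879 to 87364887 in the second, and TTCCTTGAA at 87258622 to 87258630 in the intergenic region.

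**Figure D2:**
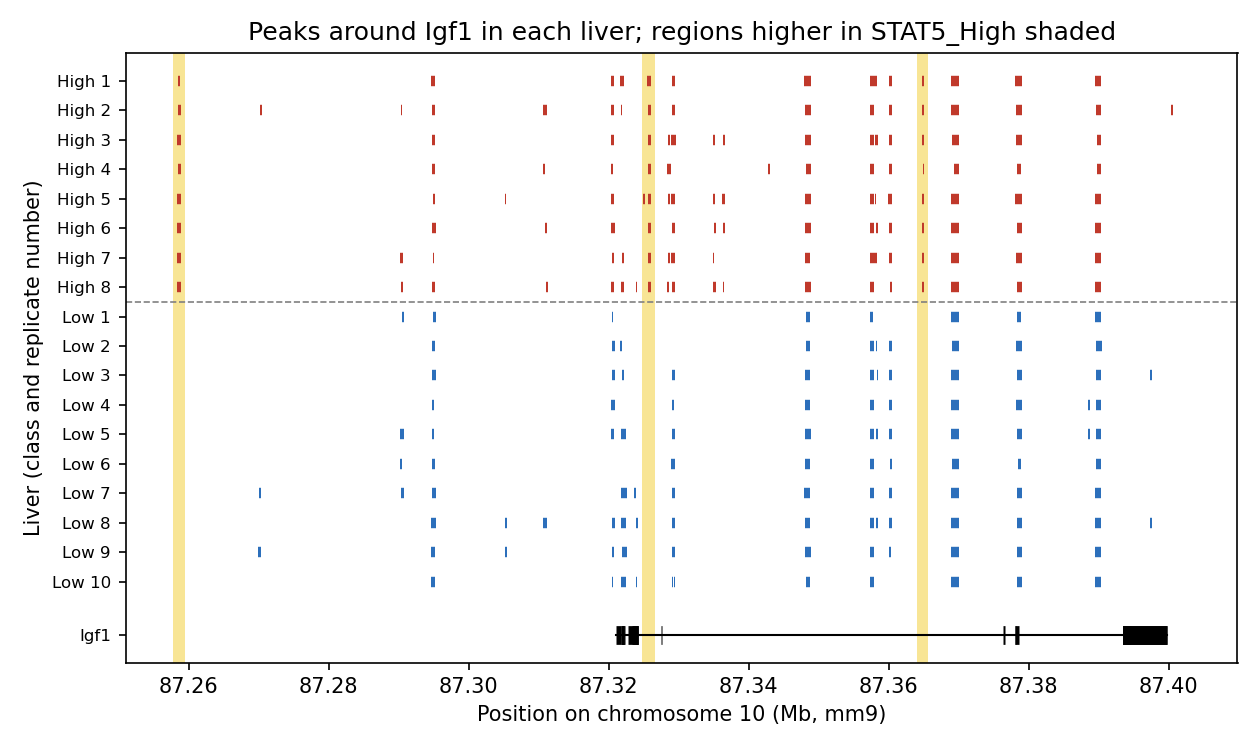
Peaks (coloured bars) of each liver around Igf1 against position on chromosome 10 (Mb, mm9), with exons as boxes below; shading marks the 3 regions called towards STAT5_High. Each shaded region holds a peak in 8 of 8 STAT5_High and 0 of 10 STAT5_Low livers, and 5 regions within 10 kb of the gene hold a peak in all 18.

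Among the STAT5 targets, 3 of 39 tested regions within 10 kb were higher in STAT5_High (7.69%, against 0.962% of other tested regions), belonging to Igf1 and Bcl6, 2 of the 13 genes with a tested region. The list did not pass (Fisher's exact p = 0.00649, adjusted p = 0.197 over 32 tests); 3 regions were called when adjusted over the list alone. The Bcl6 region was intronic (chromosome 16, 23981110 to 23981758) and had a peak in 8 of 8 STAT5_High and 1 of 10 STAT5_Low livers (exact p = 0.000411, adjusted p = 0.0370). Cish and Socs3, feedback inhibitors of cytokine signalling, each had a best region in 6 of 8 and 1 of 10 livers (Fisher's exact p = 0.0128, adjusted p = 0.181), the Cish region at its promoter. Osm followed with 7 of 8 and 2 of 10, while Stat5b (2 of 8 and 9 of 10) and Pim1 (0 of 8 and 5 of 10) leaned the other way, with adjusted p of 0.187, 0.181 and 0.303 in Fisher's exact test. The best regions of Socs2 (4 of 8 and 6 of 10), Ghr, the growth hormone receptor (4 and 8), Spry4 (3 and 7), Prlr (1 and 5), Stat5a (1 and 6) and Onecut1 (3 and 4, within 10 kb) did not pass either.

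In the hepatocyte list, 2 of 37 tested regions were higher in STAT5_High (5.41% against 0.968%; Fisher's exact p = 0.0507, adjusted p = 0.325; 3 adjusted over the list alone). A region 2268 bp from Foxa1, a forkhead factor that opens chromatin (chromosome 12, 58638655 to 58639350), was found in 8 of 8 and 0 of 10 livers. A region 828 bp from the fibrinogen gene Fgg and 9135 bp from Fga (chromosome 3, 82819803 to 82820940) was found in 7 of 8 and 0 of 10 (exact p = 0.000251, adjusted p = 0.0319). The other 12 genes with a tested region did not pass: Cebpa (3 of 8 and 10 of 10; Fisher's exact p = 0.00654, adjusted p = 0.137) and Fgb (8 and 3; adjusted p = 0.115 in the exact test) were nearest, followed by Tat (0 and 5), Alb (5 and 1), Hnf4a (2 and 8) and Cps1 (1 and 5). Apoa1 (6 and 7), Apoa2 (5 and 7), Apob (3 and 5), Ttr (3 and 3) and Tdo2 (4 and 8) had adjusted p of 0.673 or above in Fisher's exact test.

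Male-biased liver genes had 3 of 51 tested regions higher in STAT5_High (5.88% against 0.963%; Fisher's exact p = 0.0136, adjusted p = 0.197; 7 adjusted over the list alone), those of Cyp7b1, Lifr and the complement gene C8a (intron, chromosome 4, 104512664 to 104513240, 8 of 8 and 0 of 10 livers). Female-biased genes had 0 of 42, and the difference between the shares of the male-biased and female-biased lists was not past the threshold (Fisher's exact p = 0.249). The growth hormone and IGF axis had 2 of 25, both at Igf1 (adjusted p = 0.197 in Fisher's exact test; 5 adjusted over the list alone). Bile acid and sterol genes had 1 of 18 (Cyp7b1; adjusted p = 0.742; 1 adjusted over the list alone), and immediate early and stress genes 1 of 11, 8729 bp from Gadd45g (chromosome 13, 51952566 to 51953062; adjusted p = 0.547; over the list alone, 4 towards STAT5_High and 1 towards STAT5_Low). The circadian clock list held 1 region of 17 called towards STAT5_Low, the Hlf intron, a call lost in a logistic model with peak number and tags, chosen after the data were seen (Fisher's exact p = 0.0226, adjusted p = 0.197; 1 adjusted over the list alone). No call within 10 kb fell on lipid (0 of 28; 2 adjusted over the list alone), glucose and amino acid (0 of 17) or acute phase genes (0 of 23), nor on markers of other liver cells: macrophage 0 of 4, endothelial 0 of 25, stellate 0 of 8, cholangiocyte 0 of 10 and lymphocyte 0 of 2. No list passed in either direction.

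The STAT5 recognition sequence TTCNNNGAA lay in 130 of the 153 regions higher in STAT5_High (85.0%, 95% Wilson interval 78.5 to 89.8) and in 3356 of the 15457 tested regions without a call (21.7%), a ratio of 3.91 (Fisher's exact p = 1.56e-61). Of the 21 regions higher in STAT5_Low, 3 held it (14.3%, interval 4.98 to 34.6; Fisher's exact p = 0.597), those at Top2b, Slc25a47 and Fam81a. The motif occurred 2.07 times per kb in regions higher in STAT5_High, 0.240 in those higher in STAT5_Low and 0.426 in regions without a call, whose median widths were 622, 579 and 566 bp. Of the 12 regions named towards STAT5_High, 10 held the motif, and those at Lifr and Gmds did not. At Bcl6, TTCCAAGAA lay at 24080815 to 24080823, 3.0 bp from the centre of the intergenic region, and TTCCCGGAA at 23981449 to 23981457 in the intronic region; at Onecut1, TTCTCAGAA lay at 74639336 to 74639344. Rearranged motifs of the same letters were in similar shares of regions higher in STAT5_High and of regions without a call (CTTNNNAAG 21.6% and 20.7%, TCTNNNAGA 19% and 20%). Of the 21 regions higher in STAT5_Low, 9 held CTTNNNAAG (42.9%, interval 24.5 to 63.5; Fisher's exact p = 0.0255). With calls made without STAT5_High replicate 4, the share was 84.5% (212 of 251).

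**Figure D3:**
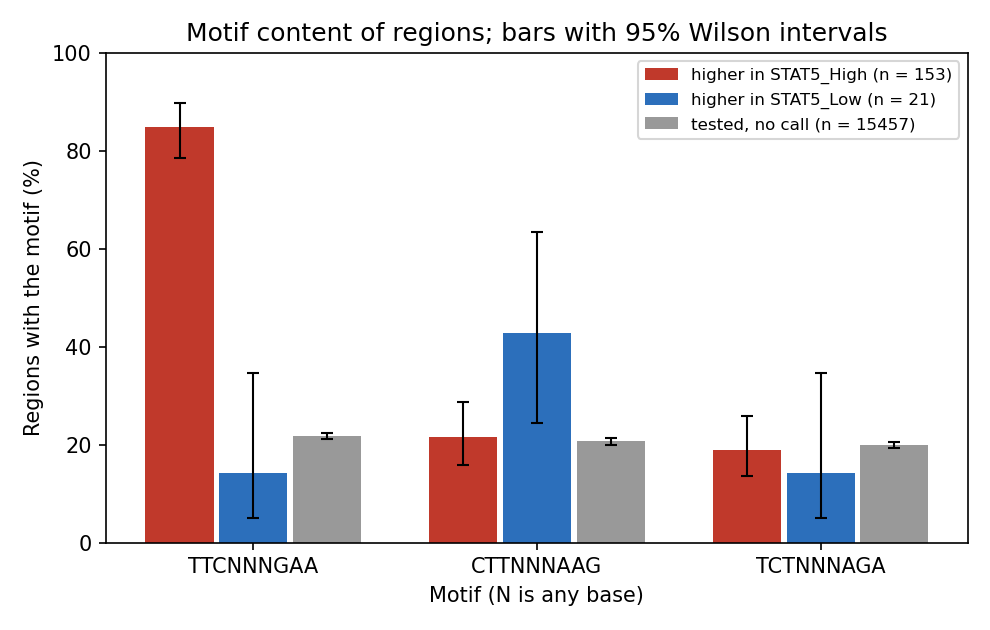
Percent of regions with the STAT5 motif TTCNNNGAA and with the 2 rearranged motifs, for regions called towards STAT5_High (n = 153), towards STAT5_Low (n = 21) and tested without a call (n = 15457); bars carry 95% Wilson intervals. The STAT5 motif stands at 85.0% in the first group and 21.7% in the last.

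Regions higher in STAT5_High lay mostly away from promoters: 72 were intronic, 70 intergenic, 5 in UTRs, 3 in coding exons and 3 (1.96%) within 1 kb of a transcription start, against 12.2% of regions without a call (Fisher's exact p = 8.27e-06). Of the 3 promoter regions, 2 were at Ddx39b and Olfr1357, named here after their values were seen. Of the 21 regions higher in STAT5_Low, 12 were intronic, 6 intergenic, 1 in a UTR and 2 (9.52%) at promoters, those of the keratin gene Krt18 and of Phf2, also named after their values were seen. The difference from regions without a call was not past the threshold (Fisher's exact p = 1.0). Chromosome 13 held 14 regions higher in STAT5_High of 722 tested, and chromosomes 1 and 2 held 13 each of 1050 and 1218. The X chromosome had 3 calls of 287 regions (1.05%) and the autosomes 171 of 15314 (1.12%; Fisher's exact p = 1.0).

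The lists of STAT5_High livers were shorter on average, without passing the threshold. They held 33383 ± 6710 peaks (SD, n = 8), against 37921 ± 4438 in STAT5_Low (SD, n = 10), a difference of -4538 (exact permutation p = 0.0976), and covered 16.7 ± 4.09 against 19.9 ± 2.99 Mb (exact permutation p = 0.0671). Median peak width was 463.5 ± 26.2 against 481.2 ± 20.1 bp (exact permutation p = 0.127). The median of the authors' fold enrichment was higher in STAT5_High, 6.13 ± 0.212 against 5.82 ± 0.323 (exact permutation p = 0.0304). This value is not scaled between libraries. STAT5_High libraries were also shallower, with 16.1 ± 1.27 (n = 8) against 18.5 ± 2.79 M tags (n = 10; exact permutation p = 0.0392). In G74A the difference in peaks turned to 1475 (exact p = 0.524), in G92 it was -9158 (exact p = 0.5) and in G99 -4383 (exact p = 0.200). These collections, of 5 to 7 livers, cannot go below an exact p of 0.0476, 0.1 and 0.1. Without STAT5_High replicate 4, which had the fewest peaks, the difference was -2436 (exact permutation p = 0.240).

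**Figure D4:**
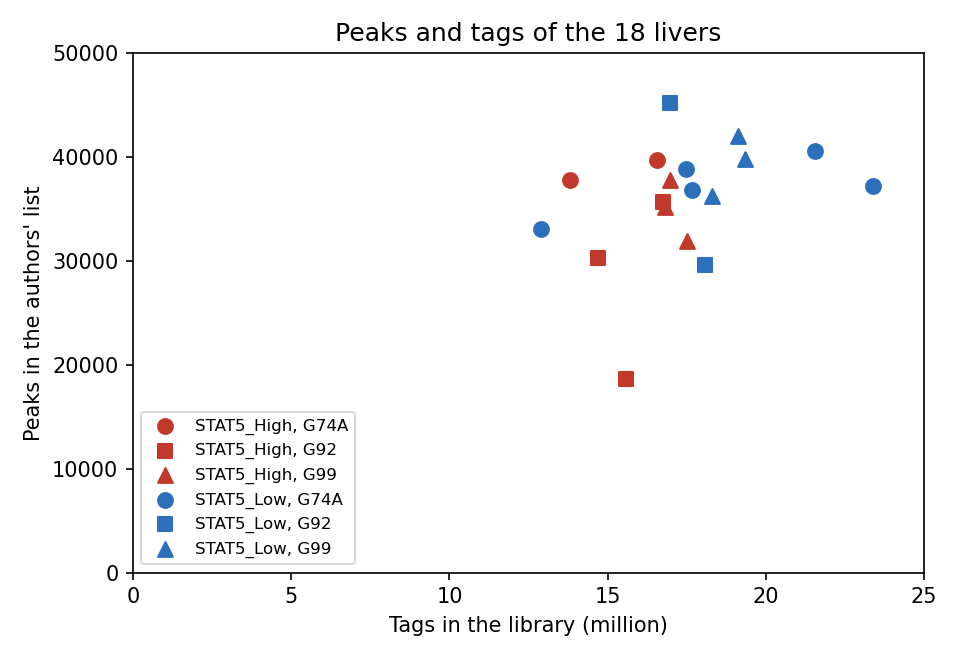
Number of peaks in each liver's list against tags in its library (M), with colour for the class and shape for the collection. STAT5_High replicate 4 has 18673 peaks at 15.6 M tags, and the other 17 livers have 29626 to 45144.

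Among the livers kept, livers of a class had more similar lists than livers of different classes. The 3 livers set aside had a profile that resembled the other class, so their removal favours this difference. The Jaccard index averaged 0.575 over pairs of a class and 0.540 over pairs of different classes, a difference of 0.0346 (exact permutation p = 0.00231). Within a class, pairs from a single collection averaged 0.602 and pairs from different collections 0.563, a difference of 0.0390 (exact permutation p = 0.00479). The class test over all livers does not hold the collections fixed. Within G74A, G92 and G99 the class differences were 0.0105, 0.00124 and 0.0400, with exact permutation p of 0.286, 1.0 and 0.1. The p of 0.1 is the smallest that the 20 assignments of G99 allow. At the stricter score the difference in G92 was -0.0071.

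The authors' combined lists of pooled reads held 64474 peaks for STAT5_High and 74451 for STAT5_Low. Of these, 4932 (7.65%) and 16225 (21.8%) had no overlap of 1 bp or more with the other list. All 153 regions higher in STAT5_High were in the combined STAT5_High list and 96 of them also in the combined STAT5_Low list, while all 21 regions higher in STAT5_Low were in both. Peaks only in the combined STAT5_High list had a peak in a mean of 12.9% of STAT5_High and 0.535% of STAT5_Low livers, and 26 of them in all 8 STAT5_High livers. Peaks only in the combined STAT5_Low list were occupied in 0.643% of STAT5_High and 4.71% of STAT5_Low livers, and 10353 of them in no single liver, against 2178 of those only in STAT5_High. The pooled STAT5_Low reads were also more numerous, 184748725 against 128701824 tags.

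By size alone, 558 regions had a peak in at least 6 of 8 STAT5_High and at most 2 of 10 STAT5_Low livers, and 520 in at least 8 of 10 STAT5_Low and at most 2 of 8 STAT5_High livers. Leaving out a liver, with shares in place of counts, gave 344 to 485 and 166 to 387. The shares tighten the bounds by construction, for example to 6 of 7 in place of 6 of 8 when a STAT5_High liver is left out.

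Regions called from 17 livers were looked up in the liver left out, among livers from which 3 with a profile against their class had been set aside. The regions called towards STAT5_High were occupied at 81.0% ± 17.6 in STAT5_High livers (SD, n = 8; 45.4 to 97.5) and 10.3% ± 11.1 in STAT5_Low livers (SD, n = 10; 1.92 to 32.7), with no overlap. Regions called towards STAT5_Low were occupied at 30.2% ± 19.4 in STAT5_High (n = 8; 4.55 to 55.8) and 72.6% ± 17.9 in STAT5_Low livers (n = 10; 37.2 to 95.5), with overlap.

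**Figure D5:**
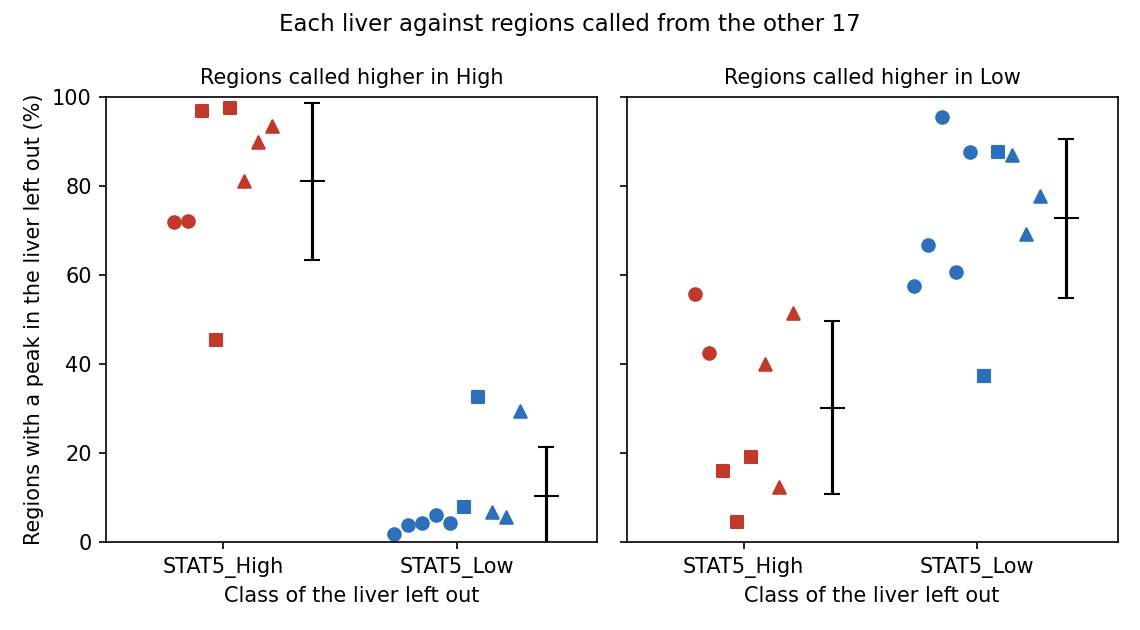
Percent of regions with a peak in the liver left out, for regions called from the other 17 towards STAT5_High (left panel) and STAT5_Low (right panel); each point is a liver, shape marks the collection, and bars are mean and SD. In the left panel STAT5_High livers lie at 45.4 to 97.5% and STAT5_Low livers at 1.92 to 32.7%.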

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

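Of the tests in this part, the one on sequencing depth was chosen only after the result was seen. A liver was singled out when its gap to the nearest liver of its class was large against the range of the class (Dixon's ratio at the 95% level), a rule that chance meets in about 1 of 20 groups. In all, 22 groups of livers were tested and 6 values were singled out, 5 of them from STAT5_High replicate 4.

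STAT5_High replicate 4 had 18673 peaks, against 30315 to 39732 in the other 7 STAT5_High livers. Its mean Jaccard index with the other livers was 0.300, and it had a peak in 65.4% of the regions found in all other livers, where each of the remaining 17 lists had 98.6% or more of its own. Of its regions 65.5% were in all 18 livers, and 8.08% were in no other liver. Shallow sequencing is argued against, since 3 livers had fewer tags and more peaks. Its share of regions in no other liver, 8.08%, was the highest of the 18, as material of another tissue or a different mix of cells would give. Its list was the shortest, though, and its share of regions in all 18 livers, 65.5%, was the highest too. Both shares are taken over its own short list, so they cannot decide. Weaker enrichment of the cut fragments stays open as well, as the peak values cannot be compared between lists. No further biological explanation was tested.

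STAT5_Low replicate 7 was singled out for regions in no other liver, 5.49%, with 45144 peaks, the most of any list.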

How the results depend on the processing

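Tests without STAT5_High replicate 4 beyond the regions that differ, and the logistic model with tags, were chosen only after the data were seen. At a stricter score 260 regions were higher in STAT5_High and 29 in STAT5_Low, and with equal numbers of top peaks 455 and 40. Fewer regions were tested (9039 and 8178 in place of 15631). Testing every region left 47 and 1, since 68362 tests were adjusted for, and testing only regions that can reach a p of 0.001 gave 201 and 40, with 8048 tested. A logistic model with the number of peaks gave 384 and 28, and with tags as well 353 and 43; the cause was not tested. Stratified by collection 0 and 0 passed (827 and 914 at an unadjusted p under 0.05), and without G74A, G92 or G99 0 and 0 each (267 and 274, 670 and 311, 188 and 227). The smallest adjusted p were 0.0775, 0.0812, 0.0706 and 0.0613, each at the smallest p that these livers allow. Such a p passes the adjustment only if enough regions reach it, and too few did (48 regions in the stratified test). The design thus limits these tests without forcing 0 calls. Leaving out each liver gave 156 to 251 regions higher in STAT5_High (251 without replicate 4) and 22 to 43 higher in STAT5_Low (43, 33, 35 and 36 without STAT5_High replicates 1, 2, 6 and 8; 33, 33 and 43 without STAT5_Low replicates 1, 4 and 6). Regions of the combined lists (150 and 20) and autosomes alone (150 and 21) kept the counts within 1.5 times, and asking for overlap of at least 0.5 of region or peak changes nothing by construction.

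The 12 regions named towards STAT5_High and the 7 more at list genes (among them Igf1, Foxa1, C8a and the Bcl6 intron) never turned direction. All remained called without any single liver, which their complete or near-complete differences largely fix. Of the 12, 10 remained called at the stricter score and 11 with equal top peaks. The 12 were picked from 47 tied regions by the rank of the authors' score, which favours them in both settings. Of all 153 regions, 73 could be tested with equal top peaks and 51 were called. Of the 7, 2 and 4 remained called in these settings, with 3 and 1 not testable. With equal top peaks Pik3c3 of the 12 and Fgg and C8a of the 7 lost the call. Without filter all 12 and 5 of the 7 remained called, and Fgg and the Bcl6 intron lost the call. The 12 regions towards STAT5_Low, Slc45a3 first, could not be tested at the stricter score or with equal top peaks, and without filter 1 of them remained called. All 12 remained called without any single liver, and 10 in the logistic model with tags, where Hlf and Rassf8 lost the call.

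Replicate numbers do not pair the livers: 3 of 8 same-numbered pairs correlated above 0.1 (-0.0771 to 0.188), and 1 of 8 STAT5_High livers correlated best with its own number. The 3 pairs above 0.1, replicates 1, 2 and 8, were those in which both livers came from a single collection. With the replicate number as a block 0 and 0 regions passed (477 and 200 at an unadjusted p under 0.05). The smallest p that this test can give is 0.00781, which passes only if enough regions reach it. With the same block, the difference in peaks per liver was -4514.5 (exact p = 0.195).

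Peaks per liver differed by 1475 in G74A, against the direction of all livers, and by -3744 with collection means removed. In each setting run its p was above 0.05. Class similarity over the livers kept passed with stricter, top-peak and region-based lists (0.0426, 0.0431 and 0.0342) and without replicate 4 (0.0245). Regions chosen by size numbered 344 to 485 for STAT5_High and 166 to 387 for STAT5_Low with a liver left out, which tightens the bounds by construction. For STAT5_Low they numbered 295 at the stricter score and 222 with equal top peaks, the cause not tested. Counting only regions overlapping the gene turned the differences for hepatocyte (-0.980 points), bile acid (-0.980) and immediate early genes (-0.979) to below 0, since their called regions lie outside the genes. The promoter difference for STAT5_Low became 1.93 points within 2.5 kb, from 21 regions, the cause not tested. At 12890880 to 23395665 tags per library, a missing peak cannot separate a closed site from a weakly open one.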

Other observations

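Tests chosen only after the result was seen were the splits of the livers for the called regions, all splits within collections, the fit of shares in livers left out on peak number and tags, the count by treatment label of the livers set aside, the search for neighbouring regions and the comparison of male-biased with female-biased genes. The genes named in the next paragraph were also picked after their values were seen.

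Besides Igf1 with 3 regions, Bcl6, Kcnj2, Nucks1, Gm17350 and ORF63 were each the nearest gene of 2 regions higher in STAT5_High. Of the 153 regions, 21 had another within 100 kb, against a mean of 4.13 and at most 19 in 10000 random draws of tested regions (0.0% of draws as high). Clustering of the tested regions alone is thus argued against. Short of the threshold, the promoter of the male-biased carboxylesterase gene Ces2b had a peak in 6 of 8 and 0 of 10 livers (Fisher's exact p = 0.00151, adjusted p = 0.0657). An intron of the insulin receptor gene Insr had a peak in 7 and 1 (exact p = 0.00288, adjusted p = 0.0996), and an intron of Egfr in 5 and 0 (exact p = 0.00654, adjusted p = 0.137). Among clock genes, Hlf apart, the best regions of Arntl (0 of 8 and 6 of 10), Nr1d1 (1 and 7) and Npas2 (3 and 9) were more frequent in STAT5_Low livers without passing (adjusted p of 0.181, 0.254 and 0.305 in Fisher's exact test).

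The regions that differed between the classes, such as those at Igf1 and Bcl6, were weighed against 4 technical explanations. A difference in enrichment between the libraries of the classes was not among them and was not tested as a cause. Median fold enrichment was 6.13 in STAT5_High against 5.82 in STAT5_Low lists (exact permutation p = 0.0304). For the livers kept, whose selection is taken up below, chance is argued against for the calls. The real classes were 1 of 100 splits with as many (153 and 21, highest other 0 and 0), the smallest share that 100 splits can show. They were also 1 of 100 splits that kept the classes' numbers within each collection (highest other 0 and 0). Both directions were adjusted together, so the 21 passed with the help of the 153. Longer lists and deeper libraries could not give the calls towards STAT5_High, whose lists were shorter on average and whose libraries were shallower. With both fitted, the share of called regions occupied in a liver left out differed by 77.4 (SE 6.90) percentage points there, which does not test them. For STAT5_Low they are argued against as the whole cause, since this difference was 32.7 (SE 7.03) with both fitted and 42.4 without. Equal numbers of top peaks, the test fixed beforehand, left only 73 of 153 and 1 of 21 testable, with 51 and 0 called. All 21 also lay in the combined STAT5_High list, so longer lists as a part of the cause stay open. A single collection is argued against too, for the livers kept. Regions picked in 2 collections differed in the same direction in the third, by at least 50 percentage points for STAT5_High and 17.2 for STAT5_Low. The livers set aside were 2 STAT5_High of G74A and 1 STAT5_Low of G92, which favours this result there. In G99, where no liver was set aside, the differences were 77.8 and 39.6 percentage points. The selection of livers cannot be told apart from the class: had the 3 livers set aside been counted with peaks as their profiles imply, a region in 8 of 8 and 0 of 10 livers would stand at 8 of 10 and 1 of 11 by their titles (Fisher's exact p = 0.00191), or 9 of 10 and 0 of 11 by their treatment labels, which conflict with the titles in 2 of the 3 (exact p = 3.40e-05), and whether the difference follows STAT5 activity or another trait of the livers stays open.

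The STAT5 motif in regions higher in STAT5_High, among them Igf1 and Bcl6, was weighed in the same way. Wider regions are argued against, since within 250 bp of the centre the share was 84.3% against 18.6% (Fisher's exact p = 2.41e-68), and base composition is too, since the larger ratio of the 2 rearranged motifs was 1.04 against 3.91. Pairs of motif arms at any spacing are argued against by ratios of 1.35 and 2.00 for spacers of 2 and 4 bases, although the spacer of 4 was itself more frequent than in regions without a call (31.4% against 15.7%; Fisher's exact p = 1.72e-06). The nearest motif of a region lay 57.3 ± 46.7 bp from the centre (SD, n = 130) against 134.5 ± 103.7 bp in regions without a call (SD, n = 3356). The permutation p was 1e-05, the smallest that 100000 resamples can give. These 130 regions held 197 motifs and the 3356 held 3905. More motifs in a region bring the nearest one closer to its centre, which was not tested apart. A candidate explanation, as a hypothesis found and tested on the same data, is that STAT5 itself binds these regions when active; binding was not measured here.

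Regions that leaned towards STAT5_High at an unadjusted p under 0.05 without a call held the motif in 606 of 787 (77.0%), against 2598 of 13426 (19.4%) with a larger p (Fisher's exact p = 1.32e-247), which suggests that many are of the same kind as those called. Regions that leaned towards STAT5_Low held it in 152 of 1244 (12.2%; Fisher's exact p = 1.21e-10). With equal numbers of top peaks the number leaning towards STAT5_Low was 39.6% of that with all peaks, but the tested regions dropped from 15631 to 8178 as well. The share leaning towards STAT5_Low went from 8.09% to 6.13% and that towards STAT5_High from 6.01% to 11.8%, so whether longer lists account for the lean cannot be told apart. For regions chosen by size the real classes were 1 of 100 splits with as many, over all livers and within collections alike, with 558 against a highest other of 430 and 260 for STAT5_High. For STAT5_Low they were 1 of 100 in both as well, but with 520 against 513 and 463, and 222 with equal numbers of top peaks, so chance is left open there. Of the other motifs tested, Sp1 (GGGCGG) was less frequent in regions higher in STAT5_High, 7.84% against 16.9% (adjusted p = 0.0150 in Fisher's exact test). These regions were also rarer within 1 kb of a transcription start (1.96% against 12.2%) and lower in median G and C content (43.4% against 46.5%). The Sp1 difference was not tested apart from these. The lower adjusted p of the 2 directions was 0.822 for C/EBP, 0.617 for forkhead, 0.875 for CUX and ONECUT, 0.617 for AP-1 and 0.822 for HNF4. The male-biased and female-biased lists were not shown to differ (Fisher's exact p = 0.249).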
